A study of Mus musculus with 2 samples.

How the data were processed

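ATAC-seq was run on sorted nuclei of hepatic stellate cells from healthy chow-fed mice, in 2 samples of 1 group, replicates A and B. Per the labels' protocols, nuclei were released by dounce homogenisation, purified on a density gradient and sorted on mCherry-RPL10A, and libraries were made with Tn5 transposase and Nextera index primers. The protocol text also names a single-cell expression kit, whose role here is not given in the sources used here. Each sample has 1 peak list without a header line. The submitters' processing notes name STAR 2.7.0, SAMtools, Picard, bedtools, MACS2 and HOMER with no role or order, and the build mm10. Whether reads were shifted for the offset of Tn5 insertion, and how the lists were cleaned, is not given in the sources used here. The peak names inside the list of B begin with a word for oil, while its label says chow and control. The labels were followed.

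Peaks were deposited as 1 list per library. For each peak the authors deposited a fold enrichment, which is a linear ratio over the caller's local background. The lists also hold the −log10 p and −log10 q of the authors' peak caller and the offset of the summit. The deposited score is the whole part of 10 times the −log10 q in 99.9% of the entries of A. The lowest −log10 q was 3.04 in A and 3.00 in B. Some called peaks were deposited in pieces: 14 entries of A and 10 of B share their name and values with another piece. The entries thus come from 36570 and 28789 called peaks. More may have been called, since a peak removed whole would leave no name. In 23 entries of A and 22 of B the summit lies outside the interval, and 12 and 13 entries are under 100 bp wide. No values are scaled between the libraries, so fold enrichment was used within a list, for ranks, and for a ratio over shared peaks.

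The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. Coordinates are 1-based, in mm10. Gene spans came from a RefSeq gene table of the GRCm38.p6 assembly, which mm10 shares. Of 441 symbols in the lists, 441 matched, 1 of them through a synonym. The table holds no strand, exons or transcripts. The planned windows around transcription start sites were therefore replaced by windows of 1000 bp around both ends of each of 21887 protein-coding genes, and exons were not told apart from introns. A gene end is thus a start or a termination site: 22.2% of genes had a replicated peak at their lower end and 22.0% at their higher end. No genome sequence was used here, so the planned enrichment of motifs was not run.

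Overlap was an intersection of at least 1 bp, and the entry of A gave the coordinates of a replicated peak. It was set against 1000 circular shifts of one list along each chromosome. Shares have 95% Wilson intervals. Positions were set against 100 random placements of the same widths on the same chromosomes. Odds ratios within deciles of −log10 q are Mantel-Haenszel estimates.

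For each gene list, the share of members with a replicated gene-end peak and the median number of replicated peaks per locus were set against 10000 random lists of protein-coding genes of the same size, matched on decile of gene length. A percentile above or below the central 95% is described as standing apart. Genes are not replicates, so a percentile describes these libraries and no p-value is given. The 16 lists were fixed before the data were examined, from general knowledge of liver cells: stellate cell identity, stellate transcription factors, fibrogenic activation, retinoid handling, vasoactive genes, TGF-beta and BMP signalling, growth factors, 6 lists of other liver cell types, other organ lineages as the negative list, housekeeping as the positive list, and immediate early genes. The mean per locus of a list was added after the data were seen, except in the differences between lists, where it was planned.

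The genes named are, for each list, up to 4 members with the most replicated peaks in the locus, ties going to the higher fold enrichment, and up to 2 members with none, longest first. Some members that this rule takes are not reported here. The genes of the transgenes are always named. Also named are the 10 protein-coding genes with the most replicated peaks, the 10 replicated peaks with the best mean rank of fold enrichment, and the 3 best-ranked peaks of each replicate that the other lacks. Wt1, Ass1, the open ends counted in the endothelial and other-organ lists, and the genes in the closing section outside this rule were chosen after their values were seen.

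Functions were tested on simulated data. With 70.1% of entries truly shared among 36577, 70.3% were recovered. In the gene list step over 21887 genes, 20 of 20 lists of 30 genes with 2 entries added per gene were found above the central 95%, and 3 of 50 unchanged lists fell outside it. These lists were scored by their mean over randomly placed entries, so the median was not tested in this way. Alternatives were a stricter peak threshold, lists of equal length, each replicate alone, other definitions of overlap, other windows and other assignments of peaks to genes.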

Results

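Open chromatin was profiled by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into accessible DNA, in nuclei of hepatic stellate cells. These cells are the vitamin A-storing pericytes of the liver sinusoid. By the labels, the mice were healthy and chow-fed. They carried an Lrat-cre transgene and an mCherry-Rpl10a allele at the ROSA26 locus, and liver nuclei were sorted on mCherry-RPL10A. The samples were 2 replicates of 1 group, A and B, so no condition was compared with another. The data address which regions are open in both replicates and whether these lie at stellate cell genes or at genes of other liver cells. Nothing in the labels states that A and B came from separate animals, so the spread between them may be technical. The peak names of B, unlike those of A, begin with a word for oil, so a difference in treatment cannot be excluded. The depth of the libraries is unknown, because the peak lists give no read counts, and all intervals cover counting error only.

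Replicate A held 36577 entries that covered 9.44 Mb, with a median width of 232 bp. Replicate B held 28794 entries over 7.28 Mb, with a median width of 227 bp. The fold enrichment of a peak is the value of the authors' peak caller, and it is used here to describe and rank peaks. Its median was 9.97 in A and 9.56 in B. A peak of A that overlapped a peak of B by at least 1 bp is called replicated, and there were 23452 of these. The locus of a gene is its body with 20 kb on either side, and a gene end is the 1 kb around either boundary of a protein-coding gene in mm10.

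Both native loci named in the genotype, Lrat and Gt(ROSA)26Sor, were open in both replicates. Lrat, which encodes the enzyme that esterifies retinol for storage, lies on chromosome 3 from 82892582 to 82903974. A replicated peak at 82903841 to 82904162 covered its higher end, with a fold enrichment of 15.6 in A and 16.1 in B. The other replicated peak of the locus lay outside the gene at 82876362 to 82876749, with 16.0 in A and 17.3 in B. It lay within 1 kb of an end of another protein-coding gene. Gt(ROSA)26Sor, on chromosome 6 from 113067428 to 113077244, had 2 replicated peaks. It is not a protein-coding gene, and both peaks lay within 1 kb of an end of a protein-coding gene. Rpl10a, on chromosome 17 from 28328471 to 28331033, had 4. The lists do not show whether reads at these loci came from the native gene or from a transgene.

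Genes of stellate cell identity had more replicated peaks than random genes of like length. All 30 measured members had at least 1 in their locus, with a median of 4 per gene against an average of 1.36 for the medians of random lists. None of the 10000 random lists reached that median. The mean was 4.4 ± 2.5 (SD over 30 genes) against 1.85, which is 2.38-fold higher. Away from gene ends the mean was 3.27 against 0.935, or 3.49-fold higher. At gene ends the list stood less far apart: 19 of 30 members (63.3%) had a replicated peak there against 47.1% in random lists, at percentile 96.2, which is inside the central 95%. Reln, which encodes the secreted glycoprotein reelin, had the most, with 12 replicated peaks over chromosome 5 from 21884454 to 22344705. Its strongest, at 22224533 to 22224847 inside the gene, had a fold enrichment of 16.6 in A and 15.9 in B. Ank3, which encodes an ankyrin, had 8, and Ecm1, which encodes an extracellular matrix protein, had 7. Of the 7 at Ecm1, 2 lay in the gene body. With the 10000 strongest entries of each replicate, the percentile of the list median was 86.5, no longer outside the central 95%, and that of the gene-end share was 37.5. With a gene-end window of 2500 bp the latter was 99.3.

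**Figure D1:**
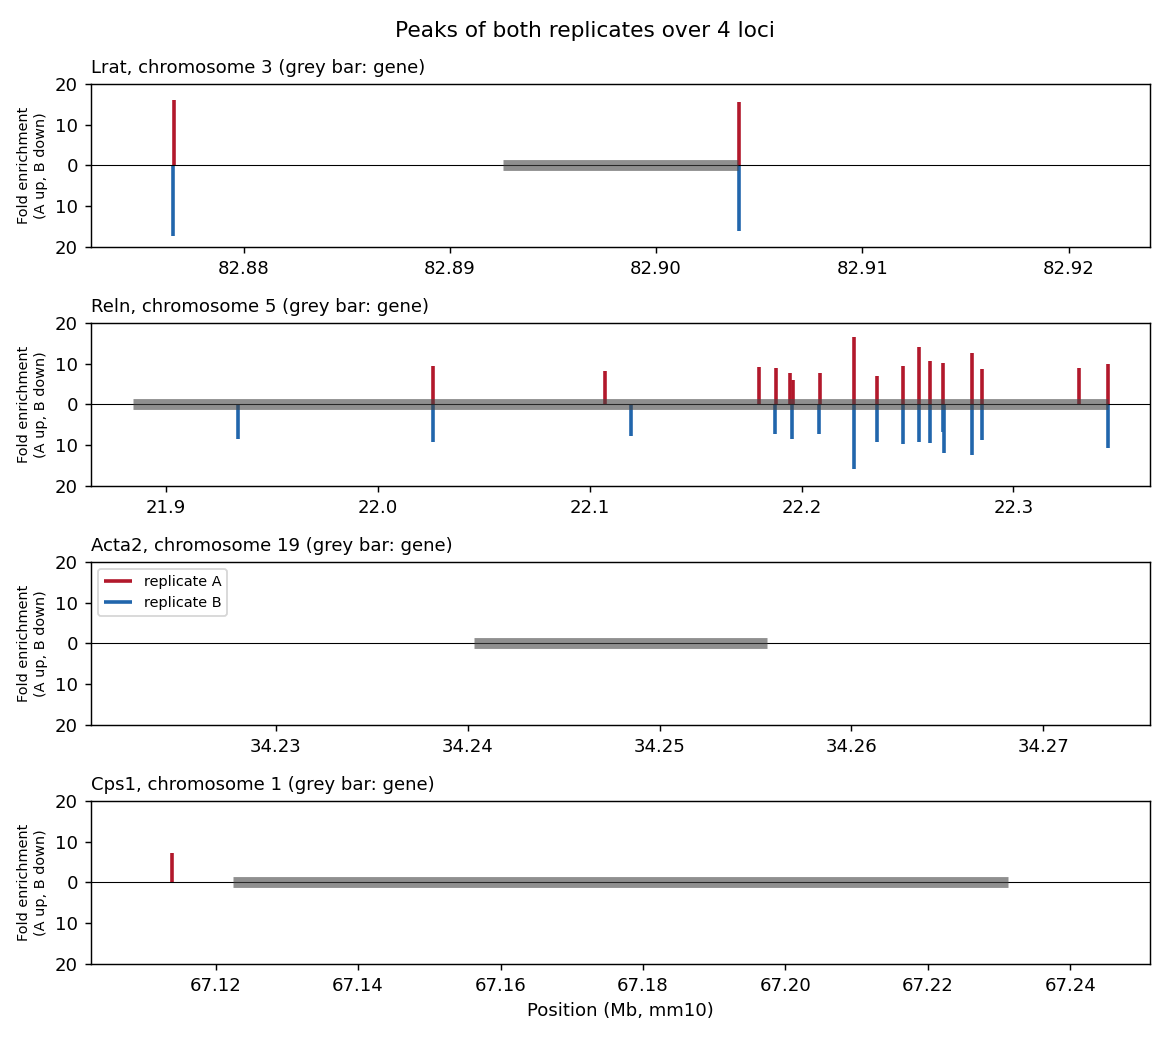
Peaks of replicate A (red, upward) and replicate B (blue, downward) at their summits over the loci of Lrat, Reln, Acta2 and Cps1, with position in Mb (mm10) on the x axis and the authors' fold enrichment on the y axis. Grey bars are the genes; Reln had 12 replicated peaks and Lrat 2, while Acta2 had no peak in either replicate and Cps1 had 1 in A alone.

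Transcription factors of stellate cells showed a like pattern. Their median was 3.5 replicated peaks per locus against 1.35, and no random list reached it. The mean was 4.29 ± 3.46 (SD over 28 genes) against 1.93. Nfia, a nuclear factor I gene on chromosome 4 from 97578066 to 98118876, had 15 replicated peaks. Rarb and Rara, which encode retinoic acid receptors, had 10 and 9, and Ets1 had 9. None of the 4 had a replicated peak at an end of its own. Of the 9 at Rara, 7 lay away from the ends of all protein-coding genes, and the rest lay at an end of another gene. The peak ranked best at Rara lay 19.9 kb outside the gene, at chromosome 11 from 98907562 to 98907864, with 25.6 in A and 20.1 in B. Of the 28 members, 25 had a replicated peak in the locus; Zeb2 and Pparg, the longest without one, had 2 peaks each in A, and Wt1 was the other. Gene ends were open at 14 of 28 members (50%) against 44.0% in random lists. The percentile of the median was 89.5 with the 10000 strongest entries of each replicate.

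Genes of retinoid handling, the storage and signalling of vitamin A, had a median of 3 replicated peaks per locus against 1.27, a value that 22 of the 10000 random lists reached. The mean was 3.86 ± 3.17 (SD over 22 genes) against 1.67. Besides Rarb and Rara, the leading members were Pnpla2, which encodes a triglyceride lipase, with 10 and the retinoid X receptor gene Rxra with 8. Only 1 of the 10 at Pnpla2 lay in the gene body, and 5 lay away from the ends of all protein-coding genes. Rbp4, which encodes the plasma carrier of retinol, had no peak in either replicate, and Aldh1a2 had 1 in A alone. Vasoactive and pericyte genes had a median of 4 against 1.38, which no random list reached, and a mean of 4.13 ± 3.21 (SD over 30 genes) against 1.93. Mylk, which encodes myosin light chain kinase, had 13 replicated peaks over chromosome 16 from 34745199 to 35002436 and its flanks. Prkg1, which encodes cGMP-dependent protein kinase, and the phosphodiesterase gene Pde3a had 10 each, and the receptor gene Adcyap1r1 had 7. Ptger3 and Vipr2, both receptor genes, had no replicated peak. Gene ends were open at 14 of 22 retinoid genes (63.6% against 45.8%, percentile 94.9) and at 17 of 30 vasoactive genes (56.7% against 46.5%, percentile 86.5), both inside the central 95%. The retinoid gene-end percentile was 97.8 with a window of 2500 bp and 98.7 without genes of several lists. With the 10000 strongest entries the medians of both lists also lay inside the central 95%, at percentiles 87.5 and 87.8, and that of retinoid genes was at 72.7 in gene bodies alone and 97.2 away from gene ends.

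TGF-beta and BMP signalling genes were open at their ends more often than random genes. Of 34 members, 25 (73.5%) had a replicated gene-end peak against 44.0%, and 3 of the 10000 random lists reached that number. The median was 3 per locus against 1.27, reached by 11 random lists, and the mean 3.21 ± 3.0 (SD over 34 genes) against 1.81. Ltbp1, whose product binds latent TGF-beta, had 14 replicated peaks over chromosome 17 from 75005480 to 75392512. The co-receptor genes Tgfbr3 and Eng had 9 and 8, and Tgfb1 had 7. Tgfb2 and the BMP antagonist gene Grem1 had no replicated peak. Above the median −log10 q of each list the gene-end percentile was 92.7 and that of the median 64.2, and with the 10000 strongest entries they were 87.0 and 90.8. In gene bodies alone the median was at 66.4.

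Growth factor ligands and receptors had a median of 2.5 per locus against 1.39, at percentile 99.7, while their mean of 2.53 ± 2.41 (SD over 38 genes) against 2.0 lay inside the central 95%, at percentile 94.5. Igf1r had 10 replicated peaks, the receptor kinase gene Axl and the cytokine gene Il34 had 7 each, and Fgf2 had 5. Of the 38 members, 11 had none, among them Ntrk3 and Pdgfc. With only the entries above the median −log10 q of each list, the percentile of the list median was 10.8. It was 87.5 with reciprocal overlap, 83.6 with 50 kb on either side and 82.1 without genes of several lists.

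Genes of fibrogenic activation and matrix did not stand apart from random genes by their median of 2 against 1.31, at percentile 87.2. The mean was 2.23 ± 1.72 (SD over 30 genes) against 1.76, at percentile 91.5. Gene ends were open at 15 of 30 members against 46.7% in random lists, at percentile 64.1. That percentile was 97.8 with replicate A alone and 1.65 with the 10000 strongest entries of each replicate. The median stood apart with replicate B alone, at 99.3, with each peak given to the nearest gene end, at 100, and when matched on gene ends, at 99.6. Away from gene ends, the mean of 1.53 against 0.817 was at percentile 98.9. Sparc, Col6a3 and Loxl1 had 5 replicated peaks each. No peak of either replicate lay in the locus of Acta2, which encodes smooth muscle actin, on chromosome 19 from 34240336 to 34255585, or in that of the cadherin gene Cdh11.

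Immediate early and stress genes were open at the ends of most members. Of 30 members, 26 (86.7%) had a replicated gene-end peak against 35.4%, and no random list reached that number. Their median was 3 per locus against 0.775, and the mean of 3.50 ± 1.74 (SD over 30 genes) was 2.83-fold higher than in random lists. Away from gene ends it was 4.94-fold higher. Junb had 8 replicated peaks, Zfp36 and Fosb 7 each and Nr4a1 6. Housekeeping genes, the positive list, were open at the ends of 25 of 30 members (83.3%) against 43.4%. Their mean of 2.63 ± 1.69 (SD over 30 genes) against 1.45 was reached by 1 random list. Their median of 2 against 1.11 was at percentile 94.3, inside the central 95%, but at 99 and 99.9 with A and B alone and 99.98 with 50 kb on either side. Hsp90ab1 had 7 replicated peaks, and Gapdh and Eef2 had 5 each. Rpl4 was the only member with none.

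Genes of hepatocytes, the main parenchymal cell of the liver, had fewer replicated peaks than random genes. Only Apoa2, Cyp2e1, Ass1 and Trf of 30 members (13.3%) had one at a gene end, against 46.3% in random lists, and 1 of 10000 random lists had as few. With replicate A alone there were 8, and with B alone 4. The median was 0 per locus and the mean 0.767 ± 1.17 (SD over 30 genes) against 1.60. The mean away from gene ends, 0.30 against 0.582, was at percentile 5.80, inside the central 95%. No peak was replicated at 17 of the 30 loci, among them that of Cps1, which encodes an enzyme of the urea cycle. Trf, the transferrin gene, had 4 replicated peaks, all outside the gene body, and Cyp2e1 had 4, of which 2 were in the body. Apoa2 had 3 and Slc10a1, a bile acid transporter gene, had 2. The median stood at percentile 0.330 of random lists, at 10.1 with replicate A alone and at up to 47.9 under the other alternatives.

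Kupffer and myeloid genes had no replicated gene-end peak at any of 27 members, where random lists averaged 42.2%, and none in a gene body. A alone had a gene-end peak at 1 member. Their mean was 0.556 ± 1.19 (SD over 27 genes) per locus against 1.51, and no random list was as low. The median of 0 lay at percentile 2.67, inside the central 95%. Their mean away from gene ends, 0.185 against 0.583, was at percentile 1.36, and no other list lay below the central 95% on that measure. Fcer1g and Cd68 had 4 replicated peaks each, Fcgr1 had 3 and Folr2 had 1, all of them outside the genes. The strongest in the locus of Fcer1g was the one inside Apoa2, its neighbour. Adgre1, which encodes F4/80, and Ptprc, which encodes CD45, had no peak in either replicate. Lymphocyte genes likewise had no replicated gene-end peak at any of 26 members, against 44.4%, while A alone had one at 3 members and B at 0. Their mean of 1.12 ± 1.34 (SD over 26 genes) against 1.61 and median of 0.5 at percentile 2.84 lay inside the central 95%, and away from gene ends the mean was 0.692 against 0.663. Tcf7 had 4 replicated peaks, 3 of them in the body, while Lck and Nkg7 had 3 each. Pax5 had no peak, and Ebf1 had 1 in A alone.

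Cholangiocyte genes had 1 open end among 20 members (5%), that of Anxa4, against 42.2%, and 2 with each replicate alone. The median was 0 at percentile 2.16 and the mean 0.600 ± 0.995 (SD over 20 genes) against 1.64. Spp1, which encodes osteopontin, had 3 replicated peaks, all outside the gene, and Cldn7, Muc1 and Anxa4 had 2 each. Pkhd1 and Sorbs2 had none. Away from gene ends the percentile of the cholangiocyte median was 45.9 and that of the mean, 0.250 against 0.704, was 3.94. Genes of portal fibroblasts, smooth muscle and mesothelium were open at an end in 6 of 26 members (23.1%) against 44.7%, at percentile 1.39, or 5.28 with the 10000 strongest entries. Their mean of 1.46 ± 1.42 (SD over 26 genes) against 1.71 did not stand apart, nor did that away from gene ends, 0.808 against 0.764. Myh11, which encodes smooth muscle myosin, had 5 replicated peaks, Eln and Des 4 each and Smtn 3. Slit2 and Muc16 had no peak.

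Sinusoidal endothelial genes were open at an end in 7 of 28 members (25%) against 45.6%, at percentile 1.34, or 5.19 with replicate A alone. The 7 were Stab1, Kdr, Gpr182, Wnt2, Esam, Bmp2 and Plvap. Their mean of 1.43 ± 2.18 (SD over 28 genes) against 1.71 did not stand apart, and neither did their median of 1, at percentile 34.3. Away from gene ends the mean was 0.929 against 0.800, at percentile 70.8. Gata4, which also stands in the list of stellate transcription factors, and Plvap had 8 replicated peaks each, Stab1 5 and Gpr182 3. Erg had no peak, and Stab2 had 1 in B alone. Genes of other organ lineages, the negative list, were open at an end in 2 of 36 members (5.56%), Sftpc and Scgb1a1, against 40.3%, and in 4 with A alone. Their mean was 0.472 ± 0.941 (SD over 36 genes) against 1.45, and 0.333 against 0.529 away from gene ends, at percentile 13.1. Cdx1 had 4 replicated peaks, the strongest of which, at chromosome 18 from 61045016 to 61045284, lies at an end of Pdgfrb. Ddx4 and Tg had 2 each, and Tyr and Mbp none.

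**Figure D2:**
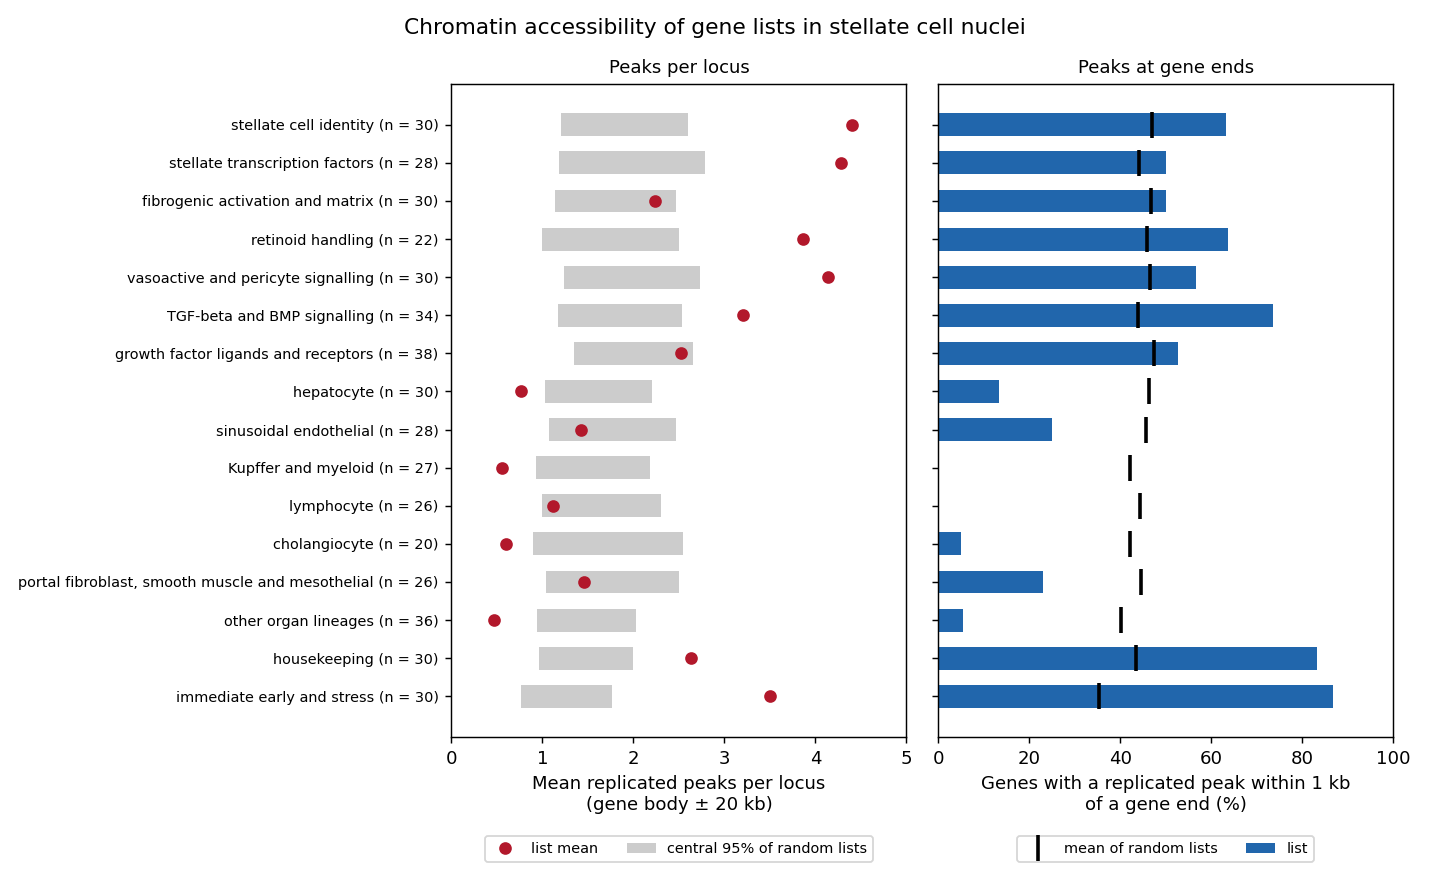
Left, the mean number of replicated peaks per locus (red points) of each of the 16 gene lists and the central 95% of 10000 random lists matched on gene length (grey bars). Right, the percentage of genes with a replicated peak at a gene end (blue bars) and the mean of the random lists (black ticks); stellate cell identity reached 4.4 peaks per locus, while Kupffer and myeloid genes had 0.556 and no open gene end.

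The difference between stellate cell identity genes and each other cell type was set against pairs of random lists. The mean exceeded that of hepatocyte genes by 3.63 replicated peaks per locus, of sinusoidal endothelial genes by 2.97, and of Kupffer and myeloid genes by 3.84. It exceeded that of lymphocyte genes by 3.28, of cholangiocyte genes by 3.80, and of portal fibroblast, smooth muscle and mesothelial genes by 2.94. Each difference of means lay above all random pairs, at percentile 100. The differences of medians ran from 3 to 4, also outside the central 95%. With the 10000 strongest entries of each replicate, the difference from portal fibroblast, smooth muscle and mesothelial genes was 0.433, at percentile 96.7, and all 6 differences of medians were 1, inside the central 95%. Of the 30 stellate identity genes, 14 also stand in another list. Over the 16 lists, 7 had a median above the central 95% of random lists and 3 below it, where chance would place 0.800 outside. With the 10000 strongest entries of each replicate, 1 lay above and 0 below. The numbers above and below were 8 and 2 with A alone and 9 and 5 with B alone. None lay below with entries above the median −log10 q, in gene bodies alone, away from gene ends, with the nearest gene end, or when matched on gene ends. Where most random medians are 0, a list median cannot fall below them. Away from gene ends, the hepatocyte median was thus at percentile 47.9.

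Genome-wide, the protein-coding gene with the most replicated peaks was Arhgap26, which encodes a GTPase-activating protein, with 24 in its locus. Of these, 23 lay in the gene body, on chromosome 18 from 38601617 to 39376285. Vps13d and the homeobox gene Zfhx3 followed with 20 each, Frmd4a with 19, Prkce, a protein kinase C gene, and Syn3 with 18 each. A peak counts for every gene whose locus it touches. The span of Vps13d holds the whole locus of Dhrs3, which had 7 replicated peaks, so these are among the 20 of Vps13d. Gse1, Wwox and the tensin gene Tns1 had 17, and Maml3, a coactivator gene of Notch signalling, had 16. All 10 are long genes, and genes of their length decile averaged 2.71. Of 21887 protein-coding genes, 9180 (41.9%) had a replicated peak at a gene end and 64.6% had one in the locus.

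Replicated peaks lay at gene ends far more often than randomly placed intervals. The share was 37.7% (95% Wilson interval 37.1 to 38.3) against 3.62% over 100 random placements, or 10.4-fold higher. Another 34.4% lay elsewhere in gene bodies and 27.9% between genes, where random placement gave 39.1% and 57.3%. The share at gene ends was 29% (28.5 to 29.4) of all entries of A and 34% (33.4 to 34.5) of B. With the 10000 strongest entries of each replicate it was 61.4%.

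The 10 strongest regions by fold enrichment were not at gene ends, unlike most of those ranked just below them. Among the 10 replicated peaks with the best mean rank of fold enrichment, none lay at a gene end and the median distance to one was 156 kb. Of the peaks ranked 11 to 100, 83 of 90 lay at a gene end. Rank 1 in both replicates was chromosome 6 from 103649311 to 103649349, 83.7 kb from Chl1, with a fold enrichment of 41.6 in A and 42.8 in B. Rank 2 in both was chromosome 12 from 3109817 to 3109920, with 40.8 and 41.5. The next by mean rank were chromosome 5 from 60042810 to 60043105 (rank 3 in A, 7 in B), and chromosome 2 from 69355477 to 69355718 (6 and 4), 13.0 kb from Abcb11. Then came chromosome 6 from 9889885 to 9890213 (10 and 8) and chromosome 12 from 97061382 to 97061834 (14 and 6). Below these stood chromosome 13 from 77438849 to 77438870 (18 and 3), chromosome 10 from 96077551 to 96077906 (16 and 10) and chromosome 2 from 57629445 to 57629779 (15 and 12). The tenth was on chromosome X from 143482944 to 143483171 (23 and 5), 35.3 kb from Pak3. Of the 10, 3 were narrower than 110 bp, against 10 of all 23355 pairs of shared peaks. How such narrow entries arose is not known, so their rank may not describe open chromatin.

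Peaks of A and B were compared to find how far the replicates shared regions. Of the entries of A, 64.1% (63.6 to 64.6) overlapped an entry of B, and 81.7% (81.3 to 82.2) of the entries of B overlapped one of A. Circular shifts of one list along each chromosome gave 0.582% on average and 0.735% at most, so the observed share was 110-fold higher. The one-sided permutation p was 0.001, the smallest that 1000 shifts can give. Shifting does not keep entries at gene ends, where both lists were enriched, so these values do not measure agreement of the replicates alone. The Jaccard index of covered bases was 0.510. Sharing followed peak strength: it went from 30.2% in the weakest decile of A by −log10 q to 99.6% in the strongest, and from 53.7% to 99.9% in B. Counting only summits within 50 bp of each other, 48.4% of A and 61.5% of B were shared.

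**Figure D3:**
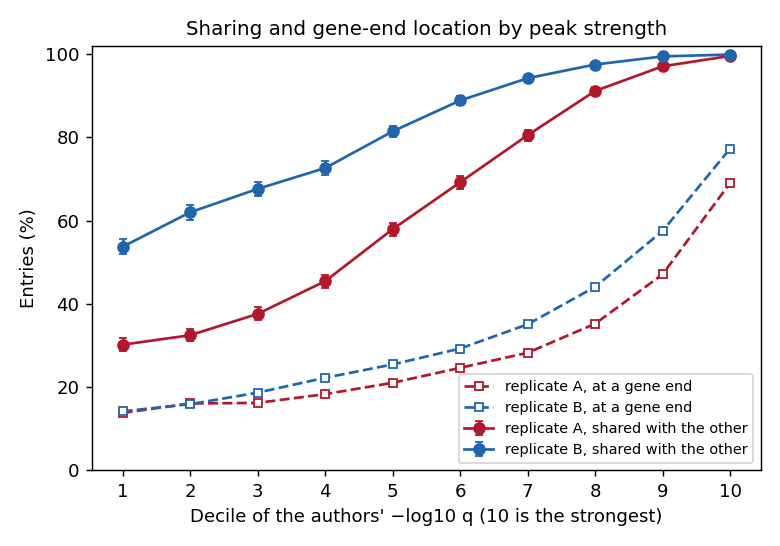
Percentage of the entries of each replicate that overlap an entry of the other (filled circles, with 95% Wilson intervals) and that lie at a gene end (open squares), by decile of the authors' −log10 q. Sharing went from 30.2% to 99.6% in replicate A and from 53.7% to 99.9% in replicate B.

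Over 23355 pairs of shared peaks, fold enrichment in A and B correlated with a Spearman coefficient of 0.687 and, on a log2 scale, a Pearson coefficient of 0.70. These are correlations across regions, which are not independent replicates. The median log2 ratio of A over B was 0.15, with an SD of 0.39, and 98.5% of pairs lay within 2-fold of the median.

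Peaks found in 1 replicate were weaker and lay less often at gene ends. Their median fold enrichment was 7.96 against 11.9 for shared peaks in A, and 7.52 against 10.4 in B. Gene ends held 13.4% of the unshared peaks of A and 17.8% of those of B, an odds ratio of 1.40 for B over A (95% interval 1.28 to 1.53). Within deciles of −log10 q, the odds of lying at a gene end were lower for unshared than for shared peaks, with ratios of 0.466 (0.437 to 0.499) in A and 0.827 (0.760 to 0.899) in B. The strongest regions found in A alone were chromosome 2 from 22744981 to 22744995, chromosome 2 from 5379421 to 5379422 and chromosome 12 from 4417642 to 4417851. Those found in B alone were chromosome 9 from 24542201 to 24542205, chromosome 15 from 102510690 to 102510927, and chromosome 9 from 8134351 to 8134628 at an end of Cep126. Of these 6, 3 are only 15, 2 and 5 bp wide. How they arose is not known, so they may not be regions open in 1 replicate alone.

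Chromosomes differed in how many more peaks A held than B. Over all chromosomes the ratio was 1.27. It was highest on chromosomes 19, at 1.52 (95% counting interval 1.39 to 1.67), and 11, at 1.49 (1.40 to 1.58), and among autosomes lowest on chromosome 16, at 1.12 (1.03 to 1.22). Across the 19 autosomes it correlated with the density of protein-coding genes, with a Spearman coefficient of 0.667 and a Pearson coefficient of 0.642. The two-sided permutation p-values were 0.00257 and 0.00396, unchanged by Benjamini-Hochberg adjustment over the 4 relations computed. Without chromosomes 7 and 11, the farthest from the median density, the Pearson coefficient was 0.719. Chromosomes are not independent samples, and the values compare 2 libraries.

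**Figure D4:**
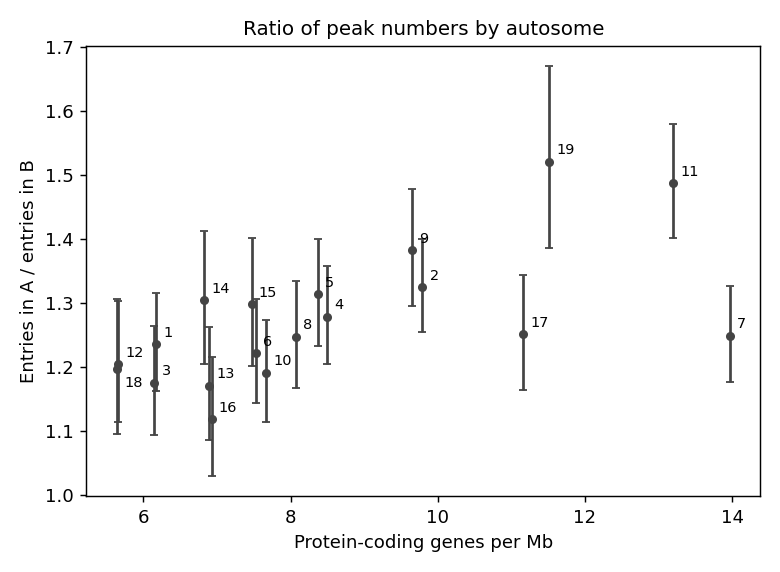
Entries in replicate A divided by entries in replicate B for each autosome (y axis, with 95% counting intervals) against protein-coding genes per Mb (x axis). Chromosomes 19 and 11 stand highest, at 1.52 and 1.49, and chromosome 16 lowest, at 1.12.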

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

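Alternatives chosen after the data were seen were the mean in place of the median, matching on gene ends, leaving out genes of several lists, leaving out entries under 100 bp, and the coordinates of B. Over 50 results, 393 of 478 values under an alternative kept their direction and side of the threshold, 50 lost the threshold, 18 passed it newly, 3 reversed and 14 moved beyond their interval. Depth is unknown and limits how many weak peaks each list holds. Leaving out a replicate gives no value for overlap or agreement, which need both. No paired analysis was possible because the labels give 1 group. The alternatives for motifs were not run, for want of a genome. With fewer peaks the medians of random lists approach 0, which limits how far a median can stand apart. For all other changes the cause was not tested.

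Overlap for A and B was 71.9% and 72.1% with the 10000 strongest entries of each, 60.3% and 76.6% with a reciprocal overlap of 50%, and 48.4% and 61.5% with summits within 50 bp. For A it was 64.7% among entries above the median −log10 q. The Spearman coefficient of fold enrichment was 0.679 with the 10000 strongest. Replicated peaks at gene ends made up 51.9% above the median −log10 q, 61.4% with the 10000 strongest, 38.7% with reciprocal overlap and 42.8% with a window of 2500 bp. With each replicate alone the share ran from 29% to 34%.

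The gene-end percentile of stellate cell identity genes was 58.5 above the median −log10 q, 37.5 with the 10000 strongest, 93.7 with reciprocal overlap, 90.3 without genes of several lists, 98.3 with a window of 500 bp, 99.3 with 2500 bp, and 96.1 to 99.2 with each replicate alone. Sinusoidal endothelial genes were at 2.73 with 2500 bp and 1.69 to 5.19 with each replicate alone. Portal fibroblast, smooth muscle and mesothelial genes were at 5.28 with the 10000 strongest and 3.20 with 2500 bp. Fibrogenic genes reversed from 64.1 to 1.65 with the 10000 strongest.

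For the median per locus, stellate cell identity genes were at percentile 86.5 with the 10000 strongest. Growth factor genes reversed from 99.7 to 10.8 above the median −log10 q and to 30.5 with the 10000 strongest. Hepatocyte genes were at 8.14 above the median −log10 q, 31 with the 10000 strongest, 19.5 in gene bodies alone, 47.9 away from gene ends, 13.1 with each peak given to the nearest gene end, 2.81 when matched on gene ends, and 0.115 to 10.1 with each replicate alone. Cholangiocyte genes were at 14.6, 34.7, 24.3, 45.9, 17.1 and 10.6 under the same alternatives in that order, 2.61 with reciprocal overlap and 3.32 without genes of several lists. Kupffer and myeloid genes were at 0.185 with 50 kb on either side, 0 by their mean, and 0.375 to 1.22 with each replicate alone. Lymphocyte genes were at 1.2 to 31.1 with each replicate alone. The difference in mean between stellate identity and portal fibroblast, smooth muscle and mesothelial genes was 0.433 with the 10000 strongest. The differences in median from hepatocyte, sinusoidal endothelial, Kupffer and myeloid, lymphocyte, cholangiocyte, and portal fibroblast, smooth muscle and mesothelial genes were 1 each with the 10000 strongest, and the last was 1 above the median −log10 q. Over 10 alternatives the 6 differences in mean stayed above 0, from 0.433 to 6.50.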

Other observations

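The bounds of the tests in this part were written before their results were seen, but chromosomes 11 and 19 were picked after their ratios were known, and setting the quotient of their windows against that of other autosomes was chosen after the result was seen. The genes in this paragraph and the next were chosen after their values were seen. Among BMP ligand genes of the TGF-beta and BMP list, Bmp10, on chromosome 6 from 87428994 to 87434512, had 5 replicated peaks, and Gdf2 and Gdf10, neighbours on chromosome 14, had 3 each. These 3 and Bmp2 had a replicated gene-end peak, while Bmp5, Bmp6 and Bmp4, with 3, 2 and 1 replicated peaks, had none at a gene end. The peak at 33923161 to 33923363 lies at an end of Gdf10 and within the 20 kb flank of Gdf2. Among inhibitor genes, Nog, Fst and Grem1 had no peak in either replicate, while Bambi, Smad6 and Smad7 had 1, 6 and 4 replicated peaks, each with one at a gene end. No difference between these groups was tested. Among growth factors secreted in the liver, Hgf had a replicated gene-end peak at 16553397 to 16553899 on chromosome 5, with a fold enrichment of 15.1 in A and 11.3 in B, and Rspo3 had 5 replicated peaks, while Igf1 had no peak.

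Several genes often used to name stellate cells or their activated state carried no replicated peak. Gfap, used as a stellate cell marker in rodents and placed here among other organ lineages, had 3 peaks in A and 0 in B. Wt1 had 0 and 2, and Timp1 had 1 and 0. Of the fibrillar collagen genes in the lists, Col1a2, Col3a1, Col5a1 and Col5a2 had a replicated gene-end peak, and Col1a1 had 2 replicated peaks, both outside the gene body.

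The number of peaks in A over that in B differed between chromosomes; a lower number of peaks passing the threshold in B would remove the relation with gene density once 10000 entries are taken from each, and it remained, with a Spearman coefficient of 0.721 (95% bootstrap interval 0.420 to 0.884) over 19 autosomes, above the 0.3 that this explanation allowed. Without chromosomes 11 and 19, the ratio of A over B was 1.11 times higher (1.06 to 1.16) in the 513 most gene-dense than in the 525 least gene-dense windows of 1 Mb. A bias that follows gene density would produce this. So would any other cause that follows gene density, since the windows show the same relation in the same lists at a finer scale. This value thus does not tell them apart. A gain of chromosomes 11 and 19 in the nuclei of A would leave their gene-poor windows as high as their gene-rich ones, and that quotient was 0.986 (0.85 to 1.1), an interval that also holds the 0.928 (0.900 to 0.955) of the other autosomes. Against other autosomes, their ratio was 1.25 times higher (1.08 to 1.43) in gene-poor and 1.18 times higher (1.13 to 1.22) in gene-rich windows. The first value passes the bound for a gain written beforehand, but the chromosomes were picked for a high ratio, so a gain stays open and no biological explanation from the design was tested.

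Fold enrichment at gene ends stood lower in A relative to B than at other shared regions, with a median log2 ratio of A over B of 0.13 against 0.17. A compressed scale in one library could produce this, and would leave an average difference under 0.05 within deciles of fold enrichment. The average was -0.0799 (bootstrap interval -0.0934 to -0.0655), negative in 10 of 10 deciles. It falls short of the 0.1 written beforehand as the bound against a compressed scale, but its interval lies wholly beyond the 0.05 that such a scale allows, and the gap without deciles was smaller, at -0.0411. This argues against a compressed scale as the whole cause. From the weakest to the strongest decile, the median log2 ratio rose from -0.0288 to 0.155 at gene ends. Elsewhere it rose from 0.0249 to 0.237 in decile 5 and stood at 0.174 in the strongest. Gene ends held 420 pairs in the weakest decile and 1867 in the strongest. Taking deciles into account thus widened the gap. The trend elsewhere did not run in one direction, so whether a compressed scale plays a part was not settled. No other explanation was tested.

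Endothelial nuclei among the sorted nuclei may account for the open ends of some sinusoidal endothelial genes. Of 12 genes fixed as most restricted to endothelium, 2 had a replicated gene-end peak, Stab1 and Gpr182, between the bounds of 6 for this explanation and 1 against it. The others, Stab2, Clec4g, Lyve1, Pecam1, Tek, Tie1, Oit3, Fcgr2b, Cdh5 and Erg, had none, and 3 of the 28 genes of the full list stand in another list. Stab1 had 5 replicated peaks, none of them in the gene body. The sort on mCherry-RPL10A selects nuclei with the label. The peak lists do not show how complete it was or whether endothelial nuclei carry the label. The number of genes is too small to decide. Random lists matched to the full list averaged 45.6%, near the share that the bound of 6 asks for. Reaching that bound would thus not have told endothelial nuclei from random genes, so the test cannot decide.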
